A study of Drosophila melanogaster with 3 samples.

How the data were processed

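Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole *Drosophila melanogaster* embryos of both sexes aged 4 to 20 h. The embryos came from a transgenic line that carries the transcription factor Scalloped (sd) with green fluorescent protein fused to its C terminus, and the tagged protein was precipitated with an antibody against GFP, per the labels. Chromatin was sheared by sonication to a size range of 200 to 800 bp, per the labels. The 3 samples are biological replicates of a single group, each from its own biosample per the labels. No second group exists, so no contrast between conditions was made.

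The deposited files were peak lists on the dm6 assembly, 1 for each replicate, 1 for the pooled replicates and 1 thresholded on the irreproducible discovery rate (IDR), which keeps peaks that rank alike in replicates. Per the file headers, each list was derived from alignments to dm6 set against a single control alignment, which was not analysed here. The aligner, the peak caller and the IDR threshold were not given in the sources used here. Each peak carried a signal value set by the authors' caller, on a scale that differs between lists, so it was used within a list, to rank peaks and for ratios between peaks, and not to compare lists. Whether it is proportional to occupancy is unknown. The deposited −log10 q value reached its ceiling of 4.38 for 100% of the IDR peaks, so it did not order them. The p-value column held no values and was not used. Each replicate list and the pooled list held exactly 30000 peaks, for a reason not given in the sources used here, so the number of peaks does not measure a replicate's depth. The IDR list held 10553 peaks and was the same as the top 10553 peaks of the pooled list by signal value. The files gave no read totals, so the sequencing depth per sample is unknown and no counting interval was put on the signal values.

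Chromosome arms 2L, 2R, 3L, 3R, 4 and X were used, and no list had a peak on Y. Genes came from Ensembl release 115 on BDGP6.54, whose coordinates are those of dm6, and positions are 1-based. Summits of different lists were called shared within 100 bp. To compare replicates, the top 10553 peaks of each were taken, and overlap was set against 1000 random placements of the second set on the same arms, with a one-sided permutation p whose smallest value is 0.000999. Each summit was assigned to the first class that applied: within 500 bp of a transcription start site (TSS), 5' UTR, coding sequence, 3' UTR, other exon, intron, intergenic. Shares per class and per arm were set against 1000 placements that avoided runs of N, with two-sided permutation p-values whose smallest value is 0.0020 before adjustment. Placement was uniform over the arms and not matched on open chromatin. The TSS class used all annotated genes except transposable elements, and the nearest gene was taken among protein-coding genes and the bantam microRNA gene (mir-ban). Both of these rules were set after the files had been seen.

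Motifs were searched on both strands within 100 bp of the summit and in windows of the same size 1000 to 1200 bp to either side, leaving out flanks within 500 bp of another IDR summit. Two-sided Fisher's exact tests were adjusted by the Benjamini-Hochberg method over 15 motifs, and over 30 tests where TSS peaks and other peaks were taken apart. The core site of TEA-domain factors was taken as CATTCC, with CTACTC, a permutation of its letters, as a control. The share by signal value was tested with a permutation test for trend over 100000 resamples. For 24 gene lists, fixed before the data were examined, the percent of genes with an IDR summit within 1000 bp of a TSS was compared with 10000 random lists matched on number of TSSs and gene length, among 13946 genes. These two-sided permutation p-values were adjusted over the 24 lists. Shares of peaks and genes have 95% exact Clopper-Pearson intervals, which treat neighbouring peaks and related genes as independent and therefore cover counting error only. Symbols that had been renamed in the annotation were updated for 5 genes. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

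The procedures were tested on simulated data. A planted replicate overlap of 39.2% was recovered as 40.2% over 10553 summits, and a planted motif share of 18.7% as 18.9% over 10552 windows. At random positions, 5% of 20 draws passed the motif test, 2% of 200 random gene lists passed the list test and 4.29% of 140 annotation classes passed theirs. Of 100 simulated lists of 30 genes with a summit at 60% of them, 99 passed before any adjustment. Their genes were drawn from all genes, of which 30.5% had a summit. Matched random lists had higher shares for many of the 24 lists, such as 44.5% for Hippo pathway and 51.9% for somatic muscle genes. The power for such lists, after adjustment over 24 lists, was thus not measured. Shorter lists, as most of the 24 are, were not simulated.

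The genes named in the text follow a rule fixed before the data were examined, except fz, CG5895, Mbs, Meltrin, Gpat4 and the noncoding genes, chosen after their values were seen. It goes down the IDR peaks with a summit in all 3 replicates by signal value and takes the gene with the nearest TSS, 1 peak per gene, until 25 genes are reached. It adds up to 4 genes per list with the strongest summit within 1000 bp of a TSS, and 8 genes in any case (sd, vg, yki, ex, Diap1, kibra, mir-ban and CycE). Alternatives varied the summit distance, the TSS window, the motif window and sequence, the peak set, the rule that links peaks to genes and the replicates included. Without a given replicate, peaks were kept when both others had a summit within 100 bp. Using only the strongest summit of each peak interval, and the trend without each replicate, were added after the data had been seen. The overlap of whole intervals used 100 placements, also set then.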

Results

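Scalloped is the fly TEA-domain transcription factor. It binds DNA together with Yorkie, the coactivator of the Hippo growth-control pathway, and with Vestigial in wing and muscle development. GFP-tagged Scalloped was mapped in 3 biological replicates of whole embryos aged 4 to 20 h. The IDR list held 10553 peaks in 9629 separate intervals, covering 4.12 Mb or 3.08% of the arms used. The median signal value in the IDR list was 553, and values ran from 308 to 74235. Signal values are the authors' own and are compared only within a list. The sequencing depth behind them is unknown.

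The first comparison asked whether the replicates located the same sites. The 6 strongest IDR peaks lay near Rh5, Pdk1, mld, spi, mir-ban and kibra, and the peak near Rh5 ranked first in each of the 3 replicates. The peak in kibra ranked 6 in each replicate. Overlap was the share of summits with a summit of the other replicate within 100 bp, as the mean of both directions. Among the top 10553 peaks, it was 72.3% for replicates 1 and 2, 81.1% for replicates 1 and 3, and 76.0% for replicates 2 and 3. Random placement, counted in a single direction, gave 1.60% on average, and each pair had a one-sided permutation p of 0.000999, the smallest possible. Over matched summits, Spearman's rho of signal values was 0.808 for replicates 1 and 2 (20071 summits), 0.871 for replicates 1 and 3 (22038) and 0.841 for replicates 2 and 3 (20813). Pearson's r on the log2 scale was 0.849, 0.904 and 0.876. These are correlations across peaks, which are not independent replicates. Of the IDR peaks, 9647 (91.4%) had a summit within 100 bp in all 3 replicates, 801 in 2, 101 in 1 and 4 in none. The share in all 3 fell to 67.4% when only the top 10553 peaks of each replicate were searched.

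Genes of the Hippo pathway and described targets of Yorkie with Scalloped were among those with the strongest peaks. The peak with its summit at 642930 on 3L (dm6, interval 637419 to 643600) ranked 5 and lay 722 bp downstream of the 5' end of mir-ban, the growth-promoting bantam microRNA gene, in an exon of the noncoding gene lncRNA:CR43334. In kibra, which encodes an upstream activator of the Hippo kinase cascade, an intronic summit at 14714331 on 3R (14712625 to 14715394) ranked 6, and kibra with 2000 bp on either side held 24 IDR summits. A kibra TSS was the nearest for 14 summits, and the others in this region were nearer to a TSS of Meltrin. In ex, whose product acts with Kibra, the summit at 431777 on 2L (430661 to 432418) ranked 7 and lay in the 5' UTR, 550 bp downstream of the TSS. The gene with its margins held 11 IDR summits. A summit at 24068569 on 2R (24068237 to 24069226), 84 bp upstream of the yki TSS, ranked 31 and had 2 CATTCC sites within 100 bp. The same interval held another summit, at 24068839 (rank 693), 82 bp downstream of a TSS of the neighbouring gene Gpat4. Each of these 4 strongest summits had at least 1 CATTCC site and was found in all 3 replicates.

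**Figure D1:**
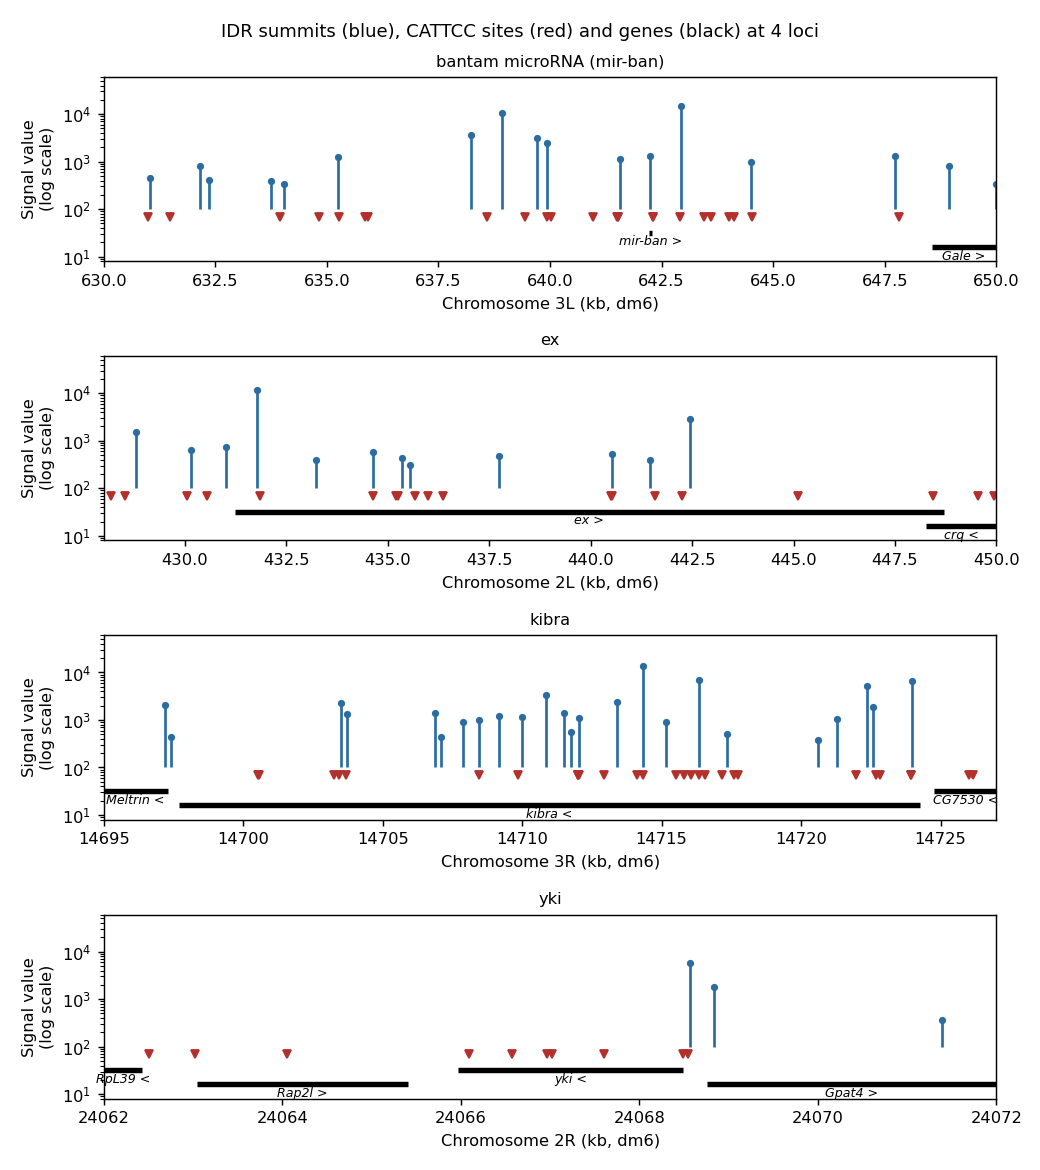
Position of IDR summits on dm6 (x axis, kb) and their signal value (y axis, log scale, blue stems drawn from the value 100) at mir-ban, ex, kibra and yki, with CATTCC sites on either strand as red triangles and genes as black bars with their direction of transcription. The strongest summits had signal values of 14840 near mir-ban, 11767 in ex, 13574 in kibra and 5853 at yki.

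The other genes named in advance had weaker peaks, counted here in the gene with 2000 bp on either side. For sd itself (X, 15804370 to 15827682), 10 IDR summits were found, not all inside the gene, and the strongest, in an intron at 15816991, ranked 530 with 2 CATTCC sites. The line carries tagged sd as a transgene, and whether this adds copies of sd sequence is unknown and was not tested. For vg, which encodes Vestigial, 4 summits were found, and the strongest, in an intron at 12895490 on 2R, ranked 1018 with 2 sites. Diap1, an inhibitor of cell death, had 11 summits, some of them outside the gene and nearer to a TSS of CG5895 or Mbs, and the strongest, in an intron at 16043444 on 3L, ranked 452 with 1 site. CycE, a cyclin for entry into S phase, had 3 summits, the strongest at rank 3621, and none had a CATTCC site within 100 bp.

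The 25 genes taken by their strongest peak, 1 peak per gene, had varied known roles and reached down to rank 31. The strongest peak, at 12012368 on 2L (12009974 to 12012989), was intergenic, 3990 bp downstream of the nearest TSS of the rhodopsin gene Rh5 and 1160 bp from the TSS of the noncoding gene lncRNA:CR44588. Its signal value of 74235 was 2.74 times that of the next peak, and the same ratio was 2.90, 2.39 and 2.77 in replicates 1, 2 and 3. The next peaks were at the promoter of Pdk1, a protein kinase, in an intron of the zinc-finger gene mld, and 464 bp downstream of a TSS of spi, which encodes an EGF receptor ligand. Further peaks lay in an intron of Mef2, a muscle transcription factor (rank 23), in an intron of shn, a transcription factor of Dpp signalling (rank 20), in an intron of sima, the fly hypoxia-inducible factor (rank 30), and in coding sequence of scrib, a cell polarity gene (rank 8). The remaining genes were tal-2A, Tim17b2, Tsp42Ef, Ctl2, Dsk, mts, Reg-2, aru, CG5902, slbo, lace, CG7120 and sky. Of the 25 peaks, 10 were within 500 bp of a TSS, 7 were in introns and 5 were intergenic, and 18 had a CATTCC site. The nearest TSS does not show which gene a peak acts on. The peaks named for Dsk, Reg-2, Pdk1 and slbo were 150, 20, 198 and 1195 bp from the TSSs of the noncoding genes CR33294, lncRNA:CR42719, lncRNA:CR45805 and lncRNA:CR44810. Those named for tal-2A, Tim17b2 and lace also had a noncoding TSS closer than that of the named gene.

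IDR summits were found mostly at TSSs and in introns and were nearly absent from coding sequence. Within 500 bp of a TSS lay 38.2% of summits, 2.80 times the random share of 13.6%. In the replicates' top peaks, the share was 39.4% ± 2.92 (SD, n = 3). Introns held 45.5%, 1.16 times random, and intergenic sequence 12.7%, 0.462 times random. Coding sequence held 33 summits (0.313%, 0.0228 times random), and 3' UTRs held 1.32% (0.303 times). For these 5 classes the adjusted permutation p was 0.0028, from the smallest p that the placements can give. The 5' UTR (0.967%, 1.25 times) and other exons (1.01%, 1.24 times) had an adjusted p of 0.032, and both calls were lost under several alternatives. With a TSS window of 1000 bp, the 5' UTR fold was 0.745 (adjusted permutation p = 0.11).

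**Figure D2:**
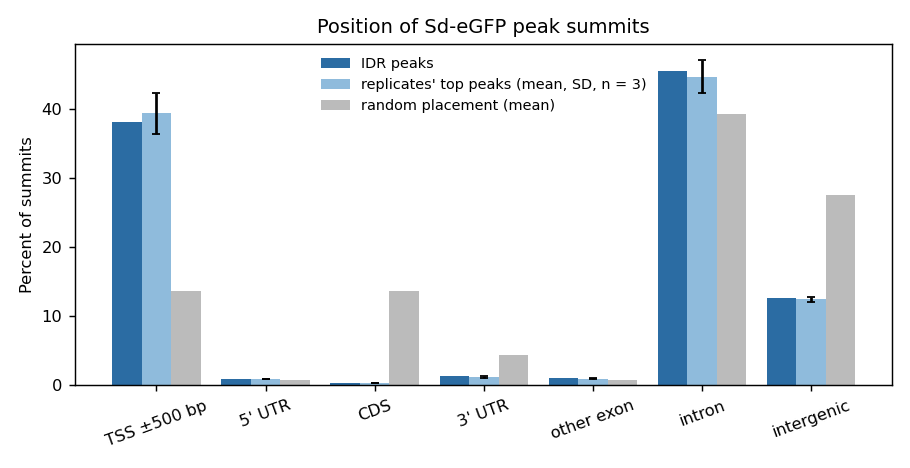
Percent of summits (y axis) in each annotation class (x axis) for the IDR peaks (dark blue), the top 10553 peaks of the replicates (light blue, mean with SD as error bars, n = 3) and random placement (grey, mean of 1000 placements). The share within 500 bp of a TSS was 38.2% against 13.6% at random, and that in coding sequence 0.313% against 13.7%.

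Peaks were spread unevenly over the chromosome arms. The X had 65.7 IDR peaks per Mb (65.2 ± 0.767 in the replicates' top peaks, SD, n = 3), 0.832 times the random value. Chromosome 4 had 13 peaks, or 9.77 per Mb (0.124 times). Arms 2R and 3L were above random, with 86.7 and 84.1 peaks per Mb (1.10 and 1.07 times). The adjusted permutation p was 0.0030 for X, 4, 2R and 3L. Arm 2L had 82.7 per Mb (adjusted permutation p = 0.050) and 3R 78.2 per Mb (0.60), neither past the threshold. The threshold was passed by 2L in the IDR peaks above the median signal (1.07 times, adjusted permutation p = 0.017). Random placement spread the total number of peaks over all arms, so the deficits on X and 4 raise the ratios of the other arms. The major autosome arms together had 82.7 peaks per Mb. The calls on 2R, 3L and 2L are thus not separate from the X deficit, and these arms were not tested against each other.

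Some windows of 100 kb held dense clusters of summits, among them those with mir-ban, ex and kibra. Of 1342 windows of 100 kb, 32 held more than 25 summits, the most seen in any window under random placement. The densest window, 600001 to 700000 on 3L, held 46 summits and contained mir-ban. The windows with ex (400001 to 500000 on 2L) and kibra (14700001 to 14800000 on 3R) held 36 and 34. The other 7 of the 10 densest windows held 32 to 37. Each window also held other genes. With 2000 bp on either side, mir-ban held 3 IDR summits and ex 11, so most summits of their windows lay elsewhere. A link between summit density and these genes was not tested.

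The TEA-domain core site was enriched at the summits. CATTCC lay within 100 bp of 19.8% of IDR summits (95% interval 19.1 to 20.6%, exact Clopper-Pearson) and in 8.67% of flank windows (8.23 to 9.12%), a ratio of 2.29 (Fisher's exact test, adjusted p = 1.0e-147). In the replicates' top peaks, the share was 19.3% ± 0.964 (SD, n = 3). The longer site RCATTCCW was found at 9.24% of summits and in 2.20% of flanks, 4.20 times as often. The permuted control CTACTC was less frequent at summits than in flanks (3.63% and 4.33%, adjusted p = 0.0068 by Fisher's exact test). Of the IDR peaks, 80.2% had no CATTCC within 100 bp, counting exact matches only. Among these peaks, 24.7% had AATTCC, which differs from CATTCC in 1 base, against 11.4% of their flanks. Whether Scalloped binds AATTCC was not tested. The share was 29.3% in the strongest of 5 equal groups by signal value, then 19.7%, 18.8%, 15.2% and 16.2% in the weakest. The permutation p for trend was 2.0e-05, the smallest possible. Of the 25 peaks with the highest signal values, here counting every peak of a gene, 60% had the site, and of the top 100, 51%.

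**Figure D3:**
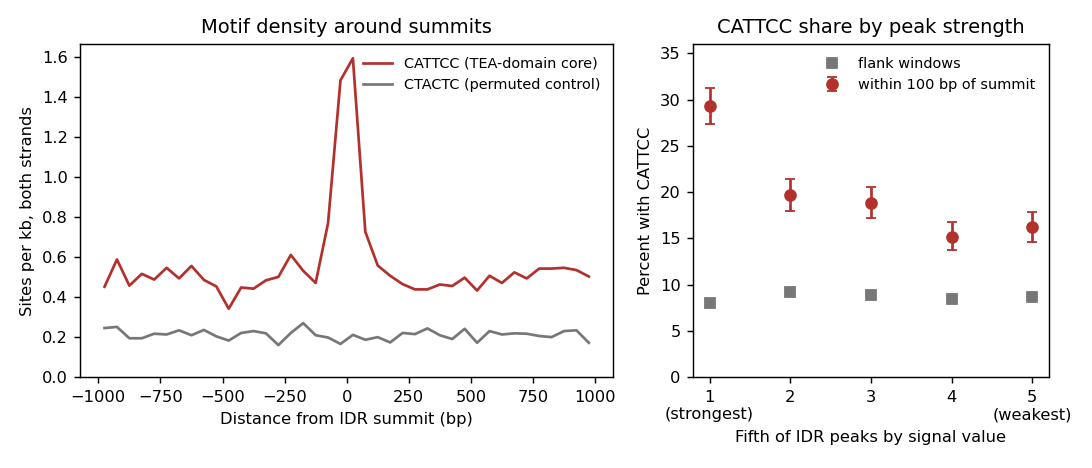
Left, density of CATTCC (red) and the permuted control CTACTC (grey) on both strands (y axis, sites per kb) in 50 bp bins by distance from the IDR summit (x axis, bp). Right, percent of IDR peaks with CATTCC within 100 bp of the summit (red, with 95% exact Clopper-Pearson intervals) and of flank windows (grey squares) for 5 groups by signal value; the share was 29.3% in the strongest group and 16.2% in the weakest.

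Sites of other factors were also compared, as descriptions of sequence and not of binding by those factors. The DNA replication-related element TATCGATA was at 2.10% of summits and in 0.488% of flanks (4.31 times), and the Grainyhead site AACCGGTT at 0.692% and 0.342% (2.02 times). GAGAG (29.3%, 1.39 times), the GATA-factor site WGATAA (27.8%, 1.25 times), the AP-1 site TGASTCA (2.85%, 1.32 times), the Mef2 site (7.58%, 1.22 times), the E-box CAYRTG (18.3%, 1.11 times) and the Su(H) site (2.31%, 1.20 times) were more frequent than in flanks, with adjusted p from 1.4e-51 to 0.038 by Fisher's exact test. The Zelda site CAGGTA was less frequent (4.23% and 4.93%, adjusted p = 0.012 by Fisher's exact test). The permuted control had a ratio of 0.838, so ratios of that size arose without a known site. The initiator TCAGTY, TAATTA and the POU-domain site ATGCAAAT did not pass the threshold, with adjusted p of 0.29, 0.075 and 0.11 over all IDR peaks. With TSS peaks and other peaks taken apart, TAATTA was more frequent than in flanks at TSS peaks (1.19 times, adjusted p = 0.0045) and less frequent at other peaks (0.815 times, adjusted p = 6.7e-06), by Fisher's exact test. At TSS peaks TCAGTY was also more frequent (1.17 times, adjusted p = 5.3e-04 by Fisher's exact test). The Mef2 and Su(H) sites passed the threshold at TSS peaks (1.55 and 1.40 times) and not at other peaks (1.03 and 1.09 times, adjusted p = 0.65 and 0.48, Fisher's exact test). The E-box, AP-1 and Grainyhead sites passed it at other peaks (1.15, 1.38 and 2.19 times) and not at TSS peaks (1.02, 1.18 and 1.66 times, adjusted p = 0.73, 0.31 and 0.18, Fisher's exact test). The Zelda site was past it at TSS peaks (0.819 times, adjusted p = 0.046) and not at other peaks (0.890 times, adjusted p = 0.17), by Fisher's exact test. The differences between TSS peaks and other peaks were not tested for these sites.

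The last comparison asked which kinds of genes had a Scalloped summit within 1000 bp of a TSS, as 4250 of 13946 genes (30.5%) did. Of the 24 lists, 3 had more such genes than matched random lists, 3 had fewer and 18 did not pass the threshold. Random lists were not matched on gene activity or open chromatin in the embryo, so a call does not show that Scalloped selects these genes. Summits within 500 bp of a TSS also held CATTCC less often (15.8%) than other summits (22.3%). Among described Yorkie and Scalloped targets, 15 of 20 had a summit (75%, against 45.2% in matched lists, adjusted permutation p = 0.044), led by mir-ban, ex, kibra and the insulin receptor gene InR. These genes were listed because earlier work had linked them to Scalloped or Yorkie. The call was lost when any summit in the gene or within 2000 bp was counted (adjusted permutation p = 0.099, with a range of 2.1e-04 to 0.099 over the alternatives, an unmatched Fisher's exact test included). Among Wingless pathway genes, 14 of 15 had a summit (93.3%, against 49.6%, adjusted permutation p = 0.0060), led by arm, which encodes beta-catenin, Apc, arr and sgg; fz had none. This call was lost in IDR peaks above the median signal and in the top peaks of replicates 2 and 3 (adjusted permutation p = 0.31, 0.30 and 0.071, with a range of 5.0e-06 to 0.31 over the same alternatives). Among cytoplasmic ribosomal protein genes, 44 of 85 had a summit (51.8%, against 28.8%, adjusted permutation p = 0.0016), with the strongest at RpS10a, RpL23A, RpL34b and RpL30.

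The lists with fewer genes than matched lists were those of odorant receptors (2 of 59 genes, Or49a and Or88a, 3.39% against 21.0%), gustatory receptors (2 of 60, Gr63a and Gr97a, 3.33% against 24.3%) and male germline genes (0 of 19, against 22.8%; the exact 95% interval reaches 17.6%). The adjusted permutation p was 0.0016, 0.0016 and 0.045. The germline call was lost without each replicate in turn (adjusted permutation p from 0.065 to 0.071), with 500 bp (0.099), in the gene with 2000 bp (0.10), by nearest TSS (0.45), above the median signal (0.24) and in replicates 1 and 3 (0.23 and 0.17). It passed in replicate 2 (0.012) and by the unmatched Fisher's exact test (0.0046). With 500 bp, above the median signal and without a replicate, the germline fold was 0 as in the main comparison, so the p moved and the fold did not. None of these settings can add a summit to the IDR peaks, so that fold could not rise. The odorant receptor call was lost by nearest TSS (0.11) and above the median signal (0.12).

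Hippo pathway genes had a summit in 15 of 23 cases (65.2%, against 44.5%), which did not pass the threshold (adjusted permutation p = 0.13). In the top peaks of replicates 1, 2 and 3 taken alone it did, at 0.011, 0.0024 and 0.030, as by nearest TSS (0.036) and by the unmatched Fisher's exact test (0.0025). Under the other alternatives it did not (up to 0.17). The strongest were at ex, kibra, yki and the kinase gene wts. Somatic muscle genes had a summit in 21 of 29 cases (72.4%, against 51.9%), with the strongest at Tm1, how, Msp300 and Mlc1, and Dpp pathway genes in 11 of 14 (78.6%, against 46.4%), with the strongest at gbb, shn, Mad and brk. Differentiated neuron genes had one in 4 of 15 (elav, brp, fne and Syx1A; 26.7%, against 58.1%). These 3 lists had an adjusted permutation p of 0.057. Muscle genes passed the threshold in replicate 3 (0.041), without replicate 3 (0.038) and by the unmatched Fisher's exact test (2.4e-05), and otherwise did not (up to 0.31). Dpp genes passed it without replicates 2 and 3 (0.047 and 0.038) and by the unmatched Fisher's exact test (9.8e-04), and otherwise did not (up to 0.63). Neuron genes passed it, below matched lists, in replicate 2 (0.012) and not otherwise (up to 1).

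Of the remaining tissue lists, summits were found at 7 of 10 heart genes (H15, tin, mid and Doc3 strongest), 8 of 12 tracheal genes (trh, verm, rib and vvl), 6 of 9 glial genes (pnt, loco, moody and ttk), 8 of 14 epidermal and cuticle genes (ple, crb, mmy and Tsp2A) and 6 of 10 gut genes (Ptx1, cad, GATAe and srp). They were found at 4 of 17 neuroblast genes (insc, nub, mira and grh) and 3 of 14 hemocyte and fat body genes (ush, crq and srp). Of the Vestigial and Scalloped wing list, 7 of 12 genes had a summit (sd, vg, vvl and nub strongest). Summits were at 7 of 11 EGF receptor pathway genes (spi, pnt, aop and sty), 8 of 15 Notch pathway genes (H, mib1, neur and numb), 4 of 7 JAK-STAT genes (Socs36E, hop, upd2 and Stat92E), 12 of 27 segmentation genes (hry, cnc, mid and oc), 2 of 8 Hox genes (Abd-B and Ubx) and 10 of 32 proteasome genes (Rpn8, Rpn13, Prosbeta1 and Prosbeta6). None of these 14 lists passed the threshold in the main comparison, with adjusted permutation p from 0.19 to 0.996. Their matched random lists had a summit at 25.6% (proteasome) to 54.7% (Hox) of genes, with 54.0% for the wing list. The share of 30.5% over all genes is therefore not their baseline. By nearest TSS, heart (0.018), tracheal (0.018), segmentation (0.034) and Notch genes (0.030) passed it. Notch genes also did in the gene with 2000 bp (0.014), proteasome genes in replicate 2 (1.70 times, 0.036), and heart and tracheal genes by the unmatched Fisher's exact test (0.025 each). Over all alternatives the adjusted p reached 0.63 for heart, 0.79 for tracheal, 0.42 for Notch and 1 for segmentation and proteasome genes. Some genes, such as vvl, srp and mid, belong to more than 1 list. The Hippo pathway list and the list of Yorkie and Scalloped targets share genes, ex, kibra and crb among them, so their results are not separate.

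**Figure D4:**
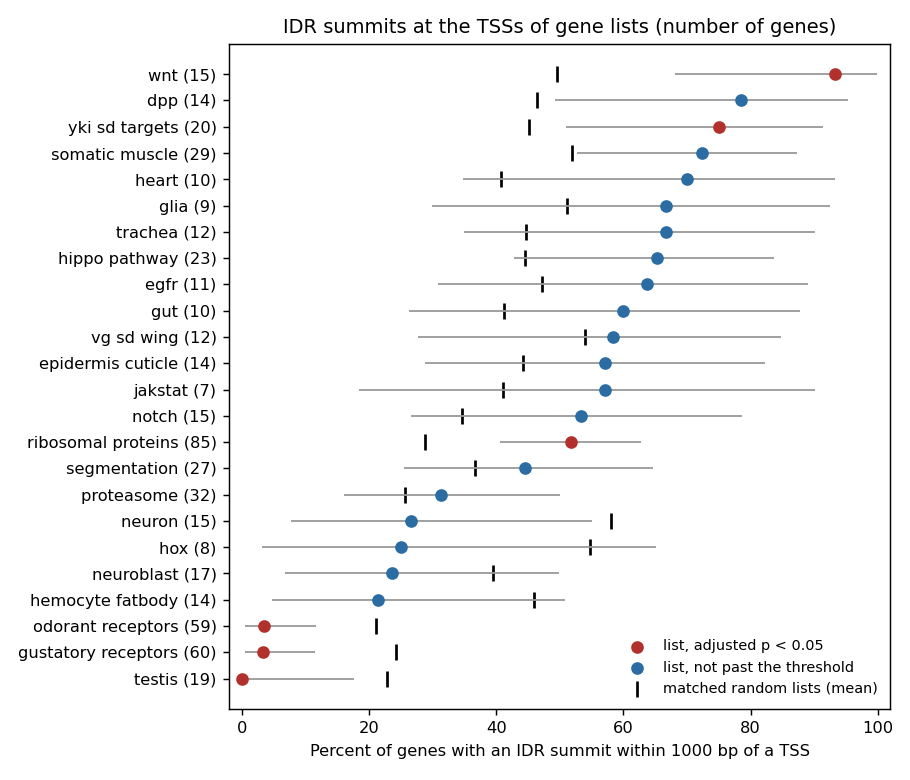
Percent of genes with an IDR summit within 1000 bp of a TSS (x axis) for 24 gene lists (y axis, number of genes in brackets), with 95% exact Clopper-Pearson intervals; red points passed an adjusted p of 0.05 against matched random lists, whose mean is the black tick. Wingless pathway genes were at 93.3%, and odorant and gustatory receptors at 3.39% and 3.33%.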

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

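Peaks outside the IDR list were searched for CATTCC after the data had been seen. Replicate summits outside that list had already entered the comparisons of replicates above. Of the 19447 pooled peaks below the IDR threshold, 14.5% had CATTCC within 100 bp of the summit, against 9.76% of their flank windows. Of 6528 summits shared by all 3 replicates and more than 500 bp from any IDR summit, 17.2% had CATTCC, against 9.58% of their flank windows.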

How the results depend on the processing

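Using the strongest summit of each interval, and the trend without each replicate, were chosen after the data had been seen. The replicate overlap, the CATTCC enrichment (ratio 1.43 to 4.20), its trend, the TSS, coding, 3' UTR, intron and intergenic classes, and the X and chromosome 4 deficits kept their direction and their side of the threshold under each alternative run. The top peaks of the pooled list are the IDR list, so that alternative moves nothing. Leaving out a replicate is also a weak alternative. For the replicate overlap it gives the value of the remaining pair. For the other results it keeps a part of an IDR list that was made from all 3 replicates. Read depth is unknown and limits every list.

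The share of IDR peaks in all 3 replicates (91.4%) was 67.4% in the top peaks of each replicate, 69.8% within 50 bp, 97.5% within 250 bp, 97.9% with any overlap and 92.8 to 94.6% without a replicate. The shares without a replicate cannot fall below 91.4%, as they ask for 2 replicates and not 3. Spearman's rho was 0.808 to 0.871 without a replicate, which are the values of the 3 pairs given above. The 5' UTR fold was 1.32 above the median signal and 1.22 by strongest summit, both no longer past the threshold, and 0.745 with a 1000 bp TSS window. The other-exon fold was 1.02 with that window, 1.32 above the median signal, 1.14 and 1.23 in replicates 2 and 3 and 1.16 by strongest summit, none past the threshold. A wider TSS window takes summits and random placements from both classes by construction, which does not by itself change a fold. The cause of the changed folds was not tested in any of these settings.

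Arm 2L passed the threshold above the median signal (1.07) and in replicate 3 (1.05). Arm 3R was at 1.02 above the median signal and 1.01 and 1.01 in replicates 2 and 3, on the other side of 1 and past no threshold in any setting. Lists above matched lists (3) numbered 8 by nearest TSS, 8 when unmatched and 3 to 5 without a replicate. Lists below (3) numbered 1 by nearest TSS and 1 above the median signal. Folds that crossed 1, none past the threshold, were 0.982 for glia (500 bp), 1.06 and 1.19 for Hox (gene with 2000 bp, nearest TSS), 1.00 for neuroblast (nearest TSS), 0.757 and 0.982 for segmentation (above the median signal, replicate 2), and 0.578 and 0.804 for proteasome (above the median signal, replicate 1). The cause was not tested. No paired analysis was possible because there is a single group.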

Other observations

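Scaling the X and the direct test of site spacing were chosen after the results they bear on had been seen. The peak counts per arm and the signal of the strongest peak were known before the tests on them were written.

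TSS peaks differed in sequence from other peaks. TATCGATA was at 4.96% of the 4029 TSS summits and 0.566% of their flanks (8.76 times), but at 0.337% of other summits and 0.435% of their flanks. CATTCC was at 15.8% of TSS summits and 22.3% of others (Fisher's exact test, p = 8.0e-17). If the base composition of promoters were the whole cause, the ratio of summit to flank was predicted to be as high at TSS peaks. Its ratio to that of other peaks was 0.738 (95% bootstrap interval 0.642 to 0.842). The prediction cannot decide this, because flanks began 1000 bp from the summit, outside the 500 bp around the peak's TSS. Promoter composition could thus lower the summit share alone. The permuted control CTACTC also had a lower ratio to flanks at TSS peaks (0.744) than at other peaks (0.931). TSS peaks were not the weaker peaks, making up 45.5% of the strongest of 5 groups by signal value and 31.4% of the weakest, and their CATTCC share was lower in 5 of 5 groups. Recovery of open promoter chromatin without a site was not tested, since no control list was analysed here, and no biological explanation was tested.

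Fewer peaks lay on X (65.7 per Mb) than on the major autosome arms (82.7 per Mb). Lower X copy number in embryos of both sexes is a candidate explanation that the data did not decide. At equal peak density, X signal was 0.785, 0.791 and 0.809 times the autosomal value at 10, 30 and 60 peaks per Mb, within a range of 0.65 to 0.85 set before the test, but a ratio below 1 near the IDR threshold follows from the deficit itself. Multiplying X signal by 1.33 gave 89.4 peaks per Mb, above the autosomes, if the signal value is proportional to copy number, which is unknown. Fewer TSSs on X were not the whole cause, since X had 0.855 times as many peaks per TSS (exact binomial p = 7.7e-09). Weaker sites on X would lower the signal in the same way and stay open.

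The strongest peak, near Rh5, stood 2.74 times above the next in signal value. Against sequence repeated elsewhere in the reference as its cause, 0% of 452 stretches of 50 bp around its summit were found elsewhere. A dense cluster of TEA-domain sites cannot be told apart from other causes: it had 2 CATTCC sites within 250 bp, between the median of 0 and the 99th percentile of 2.48 over IDR peaks. At least 2 sites were found at 673 IDR peaks (6.38%), this one included, so the number of CATTCC sites alone does not set it apart. Extra copies of this region in the line were not tested, and no biological explanation was tested.

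A hypothesis that CATTCC leads all 6-mers at IDR summits held: it ranked 1 by odds ratio (2.61), followed by AATTCC (2.49). At TSS peaks CATTCC ranked 21, with CGATAG first (3.41). AATTCC ranked 6 there (2.34). It was at 22.1% of TSS summits and 24.4% of other summits, a smaller difference than for CATTCC, which was not tested. A second hypothesis was a preferred spacing of paired TEA-domain sites. Of the spacings tested, 1 passed the threshold in peaks and not in flanks: CATTCC pairs in the same orientation with starts 7 bp apart numbered 14 of 197 in peaks (3.58 expected) and 3 of 137 in flanks. The direct comparison gave p = 0.047 by Fisher's exact test and an adjusted p of 1 over 75 comparisons, so a preferred spacing cannot be told apart from chance.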
